A study of Homo sapiens with 10 samples.

How the data were processed

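RNA was measured by sequencing in 10 samples of human heart tissue kept as formalin-fixed, paraffin-embedded (FFPE) blocks, a form of archived tissue in which RNA is broken into short pieces and chemically modified. Per the labels' protocols, RNA came from sections of each block with a Qiagen RNeasy FFPE kit, human ribosomal RNA was depleted with RiboZero Gold, and stranded total RNA libraries were made with a TruSeq kit. Total RNA libraries also carry noncoding RNA, and depletion can leave a different residue of ribosomal RNA in each library. The labels give 3 groups. Lesions of cases sampled once are called C lesion (n = 4), and cases sampled at both a lesion and a control site gave the CS lesion (n = 3) and CS control (n = 3) samples. The labels do not spell out C and CS. Apart from these case numbers nothing states that the samples came from separate donors, so p-values refer only to these samples, and part of their spread may be technical.

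The deposited table holds TPM values (transcripts per 1000000), a unit scaled to transcript length and to the total of each library, for 39037 Ensembl gene IDs. Each of the 10 columns summed to between 1000000 and 1000001. Per the submitters' processing notes, bcl2fastq 2.20, kallisto, HISAT2 and SAMtools and the builds GRCh38 and hg19 were used. Their roles, the annotation release and the step from transcripts to genes are not given in the sources used here. TPM keeps no depth, so the sequencing depth of each sample is unknown, and no counting interval or detection limit can be given. Because every library sums to the same total, an abundant RNA in one library lowers all other values in it. An exact 0 can be a failed estimate, so such genes are described as listed at 0. None of 12 housekeeping genes was listed at 0 in any library, and no pair of libraries held the same values (Spearman's rho across genes at most 0.914).

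Gene names, types and coordinates came from GENCODE 29 on GRCh38, which may not be the build behind the table. It named 34692 IDs and left 4345 unnamed. IDs on chromosome Y and XIST (423 in all) were removed first, which left 38614. Of the 31951 IDs above 0 in any library, 2916 had the same values as another ID, 1782 of them unnamed, and 867 of the tested IDs were of this kind. Such copies, HLA genes, pseudogenes and gene families are uncertain, because the assignment of shared reads is unknown. No column of other samples was present in the table.

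Values were tested as log2(TPM + 1) with limma (trend and robust variance), keeping genes with at least 1 TPM in at least 3 samples, which gave 19562 genes. Limma draws the variance of each gene toward that of genes with a similar mean level. SEs and p-values therefore rest partly on other genes, and an SE can be smaller than a gene's own samples would give. All 10 samples entered 1 fit with 3 groups and no block. The 3 comparisons were CS lesion against CS control, C lesion against CS control, and C lesion against CS lesion. The last one is the test of the difference between the others. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(TPM + 1) scale and understate changes of low genes. The first and second comparisons share their control libraries, so no overlap or correlation between them was computed.

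Before the data were examined, 39 gene lists, the tests, most of the other settings and the rule for naming genes were fixed. Lists with at least 5 tested members (38) were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. A list's mean log2 change is given relative to the mean over all tested genes. The list of RNA quality genes is void as a check, since 5 of its 20 members were in the table, under 80%, and the mesothelial list had too few tested members. The naming rule took, per direction, the 10 genes with the largest change among those past the threshold whose sample ranges did not overlap, in the first comparison also with the same sign in all 3 pairs. It left out the lowest tertile of mean level, clone-based, small RNA and pseudogene names, and immunoglobulin and T cell receptor variable segments. Where fewer than 5 genes qualified, the 5 with the smallest p were taken as values outside the rule's first part. Each list past the threshold added its 4 members with the smallest p in its direction, and any other list described added 1.

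The case numbers pair the CS samples, since the series design describes cases with both kinds of sample. Deviations from the group means correlated by 0.40, 0.50 and 0.51 across genes within the 3 numbers, and by −0.41 to 0.03 otherwise. Other settings, also chosen then, were a replicate block (fixed, or random with a correlation of 0.883), fits on both groups alone, upper-quartile, median-of-ratios and quantile scaling, no filter, a filter at 5 TPM, limma without trend, array weights, pseudocounts of 0.1 and 5, removal of mitochondrial mRNAs, and leaving out each sample. Settings chosen after seeing the data left out C lesions 2 and 3 together, or removed the MTRNR2L family and AC114801.3, IDs that resemble mitochondrial ribosomal RNA, and rescaled the rest. Library measures were compared with two-sided exact permutation tests.

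The tests were run on simulated data. With low noise, all 100 changed genes at each of log2 2 and 4 were recovered. With the noise of the real libraries, the fit of all libraries recovered 0 of 100 at log2 2 and 0 of 100 at log2 4 for CS lesion against CS control (18654 genes), and 0 and 2 of 100 for C lesion against CS control (18640 genes). Without C lesions 2 and 3 these became 3 and 52 of 100 (18316 genes), and 2 and 42 of 100 (18302 genes). In the fit of all libraries 1 of 1 and 1 of 3 calls were false, and without C lesions 2 and 3 11 of 66 and 21 of 65, above the nominal 5%, and the cause was not tested. Each gene was drawn independently around its CS control mean, without pairing, and changed genes had a mean log2(TPM + 1) above 4. The library-wide shift of C lesions 2 and 3 thus became noise of single genes. The real fits called 22 and 1206 genes, so these simulations do not give the power of the real tests. Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, BLAST+ 2.17.0, and R 4.3.3 with limma 3.58.1 and statmod 1.5.0.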

Results

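The series holds TPM values of 10 FFPE heart samples, from 4 C lesions, 3 CS lesions and 3 CS controls. The study asked which microbes were present in inflamed hearts and how the host tissue responded, and only host genes were analysed here. Sequencing depth is unknown, because TPM keeps none.

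C lesions 2 and 3 stood apart from the other libraries. They had 193 and 230 genes at 1 TPM or more, against 15485 to 20228 in the other 8. The MTRNR2L family, nuclear genes that resemble the mitochondrial 16S ribosomal RNA gene MT-RNR2, held 71.7% and 72% of their TPM, and the pseudogene AC114801.3 held 27.5% and 27.2%. In C lesion 1 the MTRNR2L family held 32.0%, and in C lesion 4 it held 1.10%. The median of 12 housekeeping genes was 0.729 and 1.02 TPM in C lesions 2 and 3, and between 197 and 702 TPM elsewhere. The share of mitochondrially encoded mRNA was 16.9% ± 15.2 (SD, n = 3) in CS lesions and 20.5% ± 15.7 (n = 3) in CS controls (exact permutation p = 0.5). That test ignores the pairing by case, and no paired test was made. In cases 1 to 3 the lesion held 8.94%, 34.5% and 7.32% and the control 12.1%, 38.5% and 10.8%, so the share was lower in each lesion. It was 2.56% ± 2.91 (n = 4) in C lesions (exact permutation p = 0.0571 against CS controls, adjusted p = 0.457). These p-values belong to a family of 12 tests of 6 library measures. The smallest p possible was 0.1 with 3 samples against 3 and 0.0571 with 4 against 3. No measure could therefore pass 0.05, and the adjusted p ranged from 0.457 to 1. The share of mitochondrially encoded mRNA did not overlap between C lesions (at most 5.45%) and CS controls (at least 10.8%). In C lesions 2 and 3 the MTRNR2L family and AC114801.3 lower this share. Of protein-coding TPM without the MTRNR2L family, it was 9.97%, 16.8%, 15.5% and 5.27% in C lesions 1 to 4. In CS controls 1 to 3 it was 12.9%, 42.7% and 12.6%, so these ranges overlapped.

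**Figure D1:**
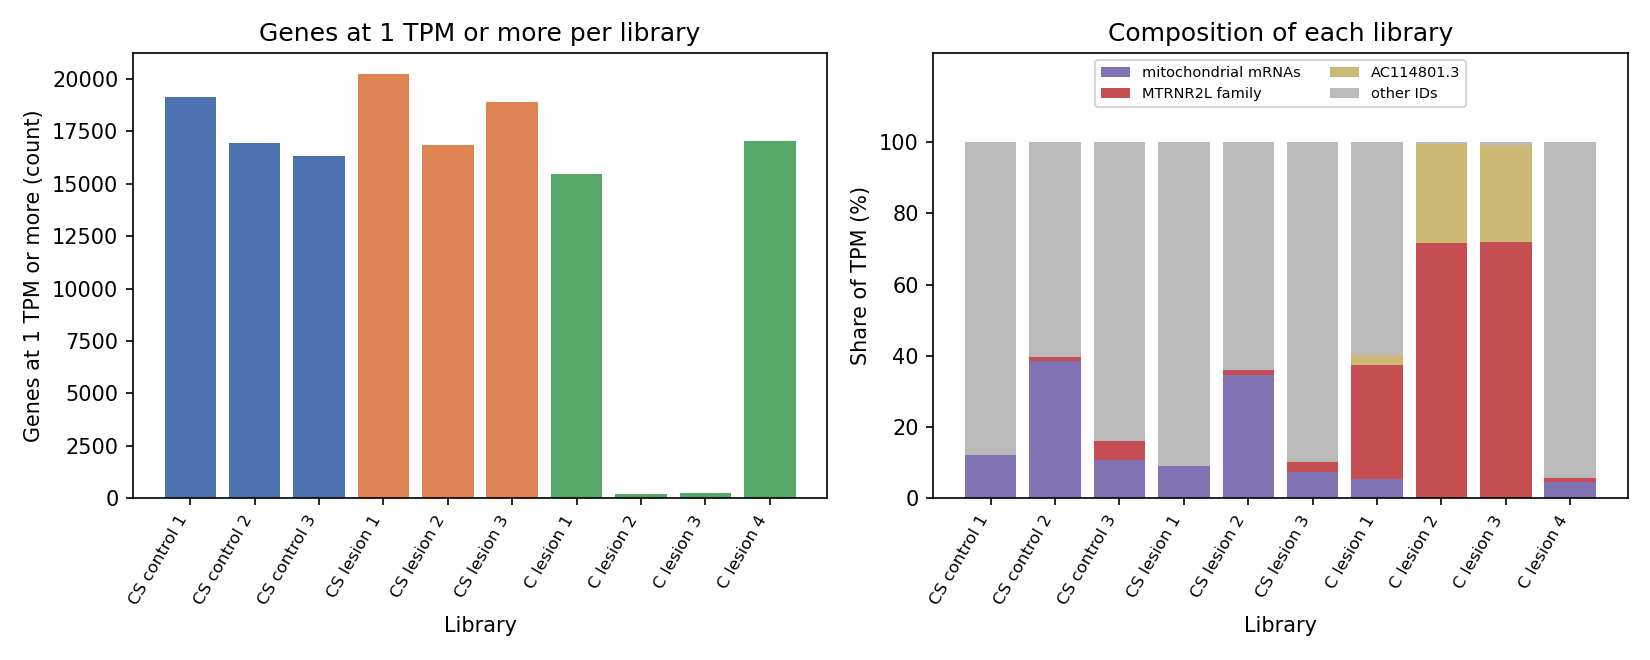
Left, genes at 1 TPM or more (count) in each library; right, the share of TPM (%) held by mitochondrial mRNAs, the MTRNR2L family, AC114801.3 and all other IDs. C lesions 2 and 3 have 193 and 230 genes at 1 TPM or more, and the MTRNR2L family holds 71.7% and 72% of their TPM.

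The comparison of CS lesion with CS control asked how lesioned tissue differed from control tissue of the same cases. Among the genes that rose in the lesions were 9 immunoglobulin and 2 T cell receptor genes. Heart muscle gene lists ranked lower by camera (for 3 of these lists, adjusted p = 0.808 with an estimated correlation). TRAJ38, a joining segment of the T cell receptor alpha locus (ENSG00000211851, 14:22502231–22502292 on GRCh38, 62 bp), rose from 1.73 ± 2.99 to 40.7 ± 17.6 TPM (SD, n = 3 each), a log2 change of 4.4 ± 1.0 (SE; limma adjusted p = 0.0143). TRAJ29, another such segment (ENSG00000211860, 14:22513939–22513998, 60 bp), was listed at 0 in all CS controls and stood at 93.2 ± 90.5 TPM in the lesions (limma adjusted p = 1.44e-05). IGHG3, the constant region of immunoglobulin G3 (ENSG00000211897, 14:105764503–105771405), rose by 4.65 ± 1.02 on the log2 scale (limma adjusted p = 0.00755). Its levels in the 3 lesions were 226, 0.0473 and 244 TPM, and the ranges of the groups overlapped. Both joining segments were listed at 0 in all 4 C lesions. Because TPM is scaled to transcript length, a few reads on such short segments can give a high value, and read numbers are unknown.

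Of 19562 genes tested, 18 rose and 4 fell, and 385 had an unadjusted p under 0.05. The 18 were 9 immunoglobulin genes, 2 T cell receptor genes, 1 other named gene and 6 IDs without a name, 5 of which had the values of a named gene in the same set. The 4 that fell, named after their values were seen, were the immunoglobulin joining segment IGHJ4 and the pseudogenes H3F3AP4, TMSB4XP6 and AC016559.1. Without C lesions 2 and 3, which share in the estimate of spread, 1 gene rose and 2 fell: TRAJ29 (adjusted p = 0.000516), IGHJ4 (adjusted p = 0.00350) and H3F3AP4 (adjusted p = 0.0278), while TRAJ38 stood at 0.0713 and IGHG3 at 1.0, with the same log2 changes and SEs of 0.85 and 2.23. Leaving out 1 library gave 0 calls without CS lesion 1 (204 at an unadjusted p under 0.05), 90 without CS lesion 2, 2 without CS lesion 3, 3, 4 and 12 without CS controls 1, 2 and 3, and 7 without C lesion 4. With the case as a fixed replicate block limma called 0 genes (1989 at an unadjusted p under 0.05), and with a random block it called 496 higher and 96 lower. Sample ranges did not overlap for 927 tested genes, or 4.74%, where chance gives 10% for unpaired samples without ties. These samples are paired by case and many values are tied at 0, so nothing is concluded from this share. Other genes with the smallest p, IGKJ5, IGKJ4, IGKJ3 and IGHG4, did not pass, at log2 changes of 5.29, 3.83, 4.57 and 3.36. On the lower side RBP2, TUBA8, SYNDIG1, SHBG and DDR1 had log2 changes of −2.36, −2.19, −1.75, −1.82 and −1.71 and did not pass (adjusted p = 1).

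Of the 38 lists, 16 were higher and 4 lower in CS lesions by camera, with 0 of these past the threshold under an estimated correlation or by fry. The median change of all genes was 0.16, which became −0.02 with upper-quartile scaling, so list means are relative to all tested genes. Plasma cell and immunoglobulin genes had a mean log2 change of 2.43, with 17 of 17 members higher (camera adjusted p = 2.14e-25; adjusted p = 0.453 with an estimated correlation). Of these, 1 gene rose over all genes tested, and 4 adjusted over the list alone, and without C lesions 2 and 3 both counts were 0. IGHM, the immunoglobulin M heavy chain, had a log2 change of 3.65 ± 0.94 (adjusted p = 0.0835), and IGLC1, a light chain constant region, 4.04 ± 1.54. T cell markers had a mean of 1.40, with 21 of 21 higher (camera adjusted p = 3.09e-19; adjusted p = 0.601 with an estimated correlation). No member passed over all genes, and 6 rose adjusted over the list alone (5 without C lesions 2 and 3). CD3E, a chain of the T cell receptor complex, stood at 19.7 ± 15.8 TPM against 1.05 ± 1.02 (log2 change 3.12 ± 0.94, limma adjusted p = 0.284), and TRAC, the T cell receptor alpha constant region, had a log2 change of 3.20 ± 1.10 (adjusted p = 0.700).

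Macrophage and monocyte markers were higher by a mean of 1.33 (25 of 26 members; camera adjusted p = 1.03e-06), and interferon gamma response genes by 1.19 (19 of 19; adjusted p = 1.45e-06). Cytotoxic and NK markers were higher by 1.10 (14 of 14; adjusted p = 5.87e-07) and MHC class II genes by 1.31 (14 of 14; adjusted p = 2.36e-05). For all 4 lists the adjusted p = 0.808 with an estimated correlation. Over all genes 0 of their members passed in limma, and adjusted over the list alone 1 cytotoxic gene rose (0 without C lesions 2 and 3). Examples were CXCL10 and CXCL9, chemokines induced by interferon gamma, with log2 changes of 2.65 ± 1.11 and 2.63 ± 1.44, the monocyte chemokine receptor gene CCR2 (1.94 ± 1.02) and GZMK, a granzyme of cytotoxic lymphocytes (2.14 ± 0.71, adjusted p = 0.594). In case 2 CCR2 stood at 1.36 TPM in the control and 0.593 TPM in the lesion, and GZMK at 0.0480 and 0 TPM. CXCL10 stood at 2.73 and 2.79 TPM there, while CXCL9 was higher in the lesion (6.75 and 16.6 TPM). HLA members of these lists are uncertain, since HLA genes share reads.

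Sarcomere and calcium handling genes, the contractile apparatus of heart muscle, were lower by a mean of −1.35 in 28 of 28 members (camera adjusted p = 4.34e-07). Nuclear oxidative phosphorylation genes were lower by −0.92 in 40 of 40 (adjusted p = 1.22e-05), and fatty acid oxidation genes by −0.83 in 23 of 24 (adjusted p = 0.000365). For all 3 the adjusted p = 0.808 with an estimated correlation, and 0 members passed in limma, over all genes or adjusted over the list alone. MYL4 and MYL7, atrial myosin light chains, had log2 changes of −1.30 ± 1.48 and −1.37 ± 1.72, and COX6A2, a muscle subunit of cytochrome oxidase, −1.41 ± 1.95. Without CS lesion 3 the sarcomere list had an adjusted p of 0.0562. Endothelial markers (−0.33, adjusted p = 0.131), erythrocyte genes (−0.41, adjusted p = 0.356) and fibroblast markers (0.28, adjusted p = 0.413) did not pass. Case 2 had smaller differences than cases 1 and 3 in the plasma cell list (0.58 against 4.0 and 3.30, not relative to all genes). The same held for nuclear oxidative phosphorylation (−0.049 against −0.72 and −1.41) and fatty acid oxidation genes (−0.14 against −0.52 and −1.26). For interferon gamma response genes case 2 had 0.26, case 3 had 1.71 and case 1 more. Case 2 was also smallest in the T cell, macrophage, cytotoxic, MHC class II and sarcomere lists. No test of this was made. Counts of members higher or lower compare group means and do not show a change in each case.

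**Figure D2:**
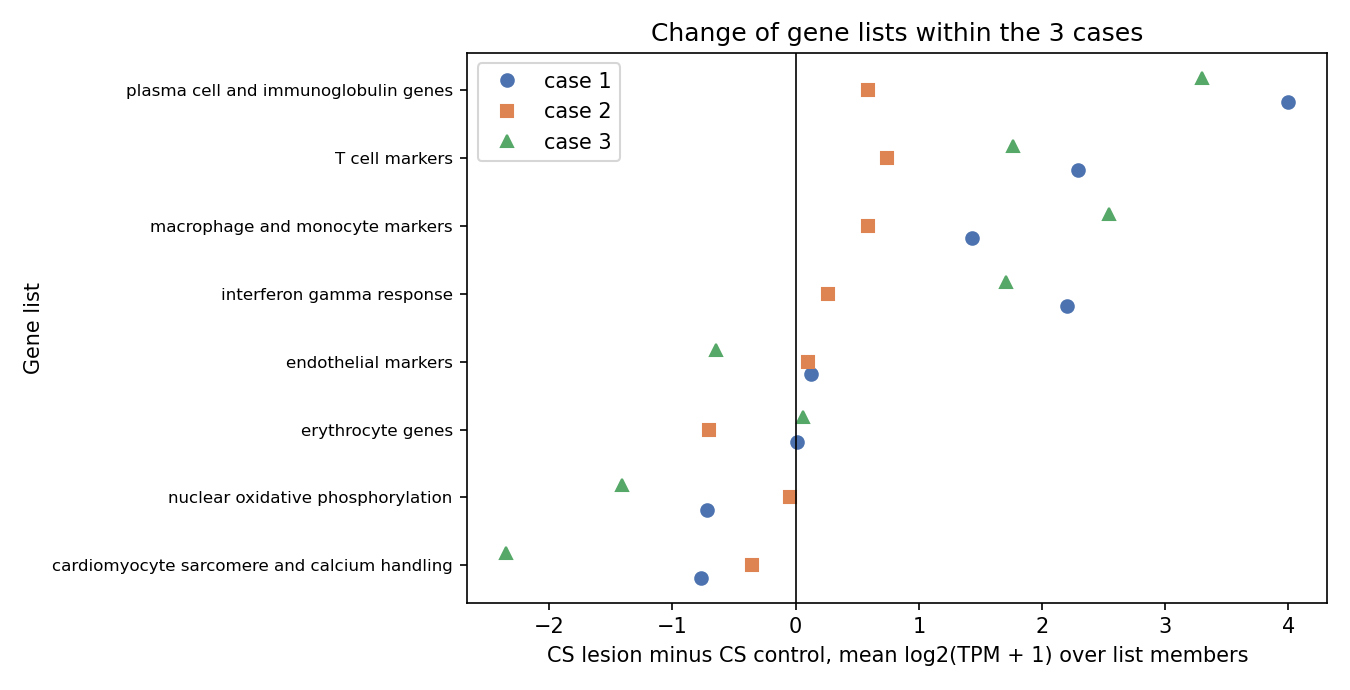
CS lesion minus CS control in mean log2(TPM + 1) over the members of 8 gene lists (rows of the plot), 1 point per case, not relative to all genes. The T cell list lies at 2.29, 0.74 and 1.76 in cases 1 to 3 and the sarcomere list at −0.77, −0.35 and −2.35.

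The comparison of C lesion with CS control set lesions of single-sample cases against control tissue of other cases. In TPM, heart muscle transcripts were nearly missing from the C lesions, though in C lesions 2 and 3 the IDs that resemble ribosomal RNA lower all such values. Of protein-coding TPM without the MTRNR2L family, the sarcomere and calcium handling list held 0.0549%, 0.0489%, 0.489% and 0.0250% in C lesions 1 to 4. In CS controls it held 3.76% to 8.90%. MYL2, the ventricular myosin light chain (ENSG00000111245, 12:110910819–110920722), stood at 0.573 ± 1.09 TPM (SD, n = 4) against 8537 ± 4737 (n = 3), a log2 change of −12.48 ± 2.36 (SE; limma adjusted p = 0.000562). MB, the oxygen store myoglobin (22:35606764–35637951), fell with a log2 change of −11.82 ± 2.25 (adjusted p = 0.000562) and TNNC1, cardiac troponin C (3:52451102–52454070), with −11.24 ± 2.15 (adjusted p = 0.000585). DES, MYH7, ACTA1, ACTC1, ANKRD1, FABP3 and HSPB7 fell, with log2 changes from −11.07 to −9.93. NPPB, the natriuretic peptide B gene, was listed at 0 in all C lesions and stood at 1072 ± 864 TPM in CS controls (adjusted p = 0.00102).

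Of 19562 genes, 18 rose and 1188 fell (6340 at an unadjusted p under 0.05), and the median of all genes was −1.72. Without C lesions 2 and 3, 562 rose and 947 fell, with a median of −0.47. The split also moved with scaling, to 346 higher and 431 lower with upper quartile (median −0.06), 209 and 896 with median-of-ratios (−0.45), and 443 and 526 with quantile normalization (0.06). With the MTRNR2L family and AC114801.3 removed, 69 rose and 559 fell. Leaving out 1 library gave 11007 calls without C lesion 4, 677, 626 and 626 without C lesions 1, 2 and 3, 105, 599 and 727 without CS controls 1, 2 and 3, and 678 without CS lesion 3. Sample ranges did not overlap for 21.7% of tested genes, where chance gives 5.71% for like libraries without ties. C lesions 2 and 3 had only 193 and 230 genes at 1 TPM or more and lay near 0 for most others. Ranges then part more easily, so nothing is concluded from this share.

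Among sarcomere and calcium handling genes, 27 of 28 fell, and 28 adjusted over the list alone (mean −7.09 relative to all genes, camera adjusted p = 5.37e-39; adjusted p = 0.311 with an estimated correlation). Without C lesions 2 and 3, 26 fell. The cardiac stress program list had 11 of 14 members that fell, 12 adjusted over the list alone (mean −5.58, camera adjusted p = 1.05e-14; adjusted p = 0.311 with an estimated correlation). Of 40 nuclear oxidative phosphorylation genes 9 fell, and 40 adjusted over the list alone (mean −3.30, camera adjusted p = 8.27e-11; adjusted p = 0.509 with an estimated correlation). Endothelial markers had 7 of 16 members that fell, such as VWF, the von Willebrand factor gene (−6.78 ± 1.72, adjusted p = 0.00651), and 13 adjusted over the list alone. Fibroblast markers had 6 of 16, such as LUM, the matrix proteoglycan lumican (−5.85 ± 1.57, adjusted p = 0.0107), and 13 adjusted over the list alone. Their means were −1.68 and −2.13 (camera adjusted p = 1.78e-05 and 5.08e-05; for both, adjusted p = 0.509 with an estimated correlation). Of protein-coding TPM without the MTRNR2L family, fibroblast markers held 0.0244%, 0.377%, 0.348% and 0.0367% in C lesions 1 to 4, against 0.0922% to 0.252% in CS controls. Endothelial markers held 0.0419%, 0.0383%, 0.0997% and 0.123%, against 0.0544% to 0.0881%. Of 27 extracellular matrix genes 6 fell, and 14 adjusted over the list alone. Their mean of −1.38 (camera adjusted p = 0.00318; adjusted p = 0.644 with an estimated correlation) turned to 0.56 with upper-quartile and 0.26 with median-of-ratios scaling, and to 0.13 with the ribosomal RNA-like IDs removed.

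Inflammatory genes were high in C lesions 1 and 4. CXCL8, the neutrophil chemoattractant interleukin 8, stood at 4266 and 25325 TPM there and at 3.48 TPM or less in every other library. IL1B, the inflammatory cytokine interleukin 1 beta, stood at 1709 and 6510 TPM, and PPBP, a platelet chemokine, at 427 and 3775 TPM. Values of C lesions 2 and 3 are lowered by the IDs that resemble ribosomal RNA. Of protein-coding TPM without the MTRNR2L family, the bacterial sensing and NF-kB list held 3.06%, 0.578%, 0.267% and 5.42% in C lesions 1 to 4. In the CS libraries it held 0.0541% to 0.107%. The shares of C lesions 2 and 3 rest on few genes, since 193 and 230 reached 1 TPM. Over all C lesions CXCL8 did not pass (log2 change 6.03 ± 2.47, adjusted p = 0.120), nor did IL1B (5.47 ± 2.70, adjusted p = 0.172), and without C lesions 2 and 3 both rose, by 12.17 (adjusted p = 3.23e-10) and 11.06 (adjusted p = 8.15e-10). BCL2A1, an antiapoptotic gene of activated leukocytes (15:79960889–79971446), rose by 4.44 ± 1.21 (adjusted p = 0.0131), and CXCL1, a neutrophil chemokine (4:73869393–73871242), by 4.45 ± 1.38 (adjusted p = 0.0422). BCL2A1 stood at 579, 0.529, 0.227 and 861 TPM in C lesions 1 to 4 and at 1.36 TPM or less in CS controls. CXCL1 stood at 536, 0.557, 0 and 770 TPM, and at 0.597 TPM or less in CS controls. For both genes the group ranges overlapped, and the rise rests on C lesions 1 and 4. MTRNR2L13 and MTRNR2L7 rose by 4.25 ± 1.28 (adjusted p = 0.0266) and 3.67 ± 1.14 (adjusted p = 0.0322), and neither passed without C lesions 2 and 3 (adjusted p = 0.275 and 0.188). Their group ranges overlapped too. CCL3, a macrophage chemokine, did not pass (4.35 ± 1.53, adjusted p = 0.0760). BCL2A1, CXCL1 and CCL3 rose without C lesions 2 and 3 by 8.94, 8.95 and 8.84 (adjusted p = 2.55e-08, 2.77e-08 and 6.40e-08), and with array weights BCL2A1 and CCL3 turned to −0.10 and −0.16. With these weights the median of all genes went to −3.04, and limma called 18188 genes lower.

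The bacterial sensing and NF-kB list ranked above other genes, with a mean of 2.98 relative to all genes (camera adjusted p = 1.92e-26; adjusted p = 0.398 with an estimated correlation). Of its 30 members 1 rose, and 0 adjusted over the list alone, against 24 and 27 without C lesions 2 and 3. Neutrophil genes had a mean of 2.83 (camera adjusted p = 3.08e-17; adjusted p = 0.398 with an estimated correlation), and 0 of 17 rose, against 12 without C lesions 2 and 3, where the adjusted p = 0.0133 with an estimated correlation. Antimicrobial effectors had a mean of 1.76 (camera adjusted p = 1.12e-08; adjusted p = 0.509 with an estimated correlation), with 0 of 21 that rose, against 8 without these libraries (adjusted p = 0.0133 with an estimated correlation). Lists of blood cells ranked higher too. Platelet genes had a mean of 2.66 (camera adjusted p = 4.45e-06; adjusted p = 0.398 with an estimated correlation) and erythrocyte genes 0.69 (adjusted p = 0.0448; adjusted p = 0.644 with an estimated correlation), and the erythrocyte mean was −0.27 without C lesion 1. Not relative to all genes, the platelet mean was 0.88 (4 of 6 members higher) and the erythrocyte mean −1.08 (7 of 9 lower). These stood beside a median of −1.72 over all genes. Without C lesions 2 and 3 they were 3.14 and 1.15. In all, 17 lists ranked higher and 9 lower, and 13 of the higher ones had a mean log2 change below 0 before it was set against all genes, 14 a median below 0, while 0 of the 17 had a mean below 0 without C lesions 2 and 3. With the 0 calls of camera under an estimated correlation stood 9 calls of fry, which does not compare a list with other genes.

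**Figure D3:**
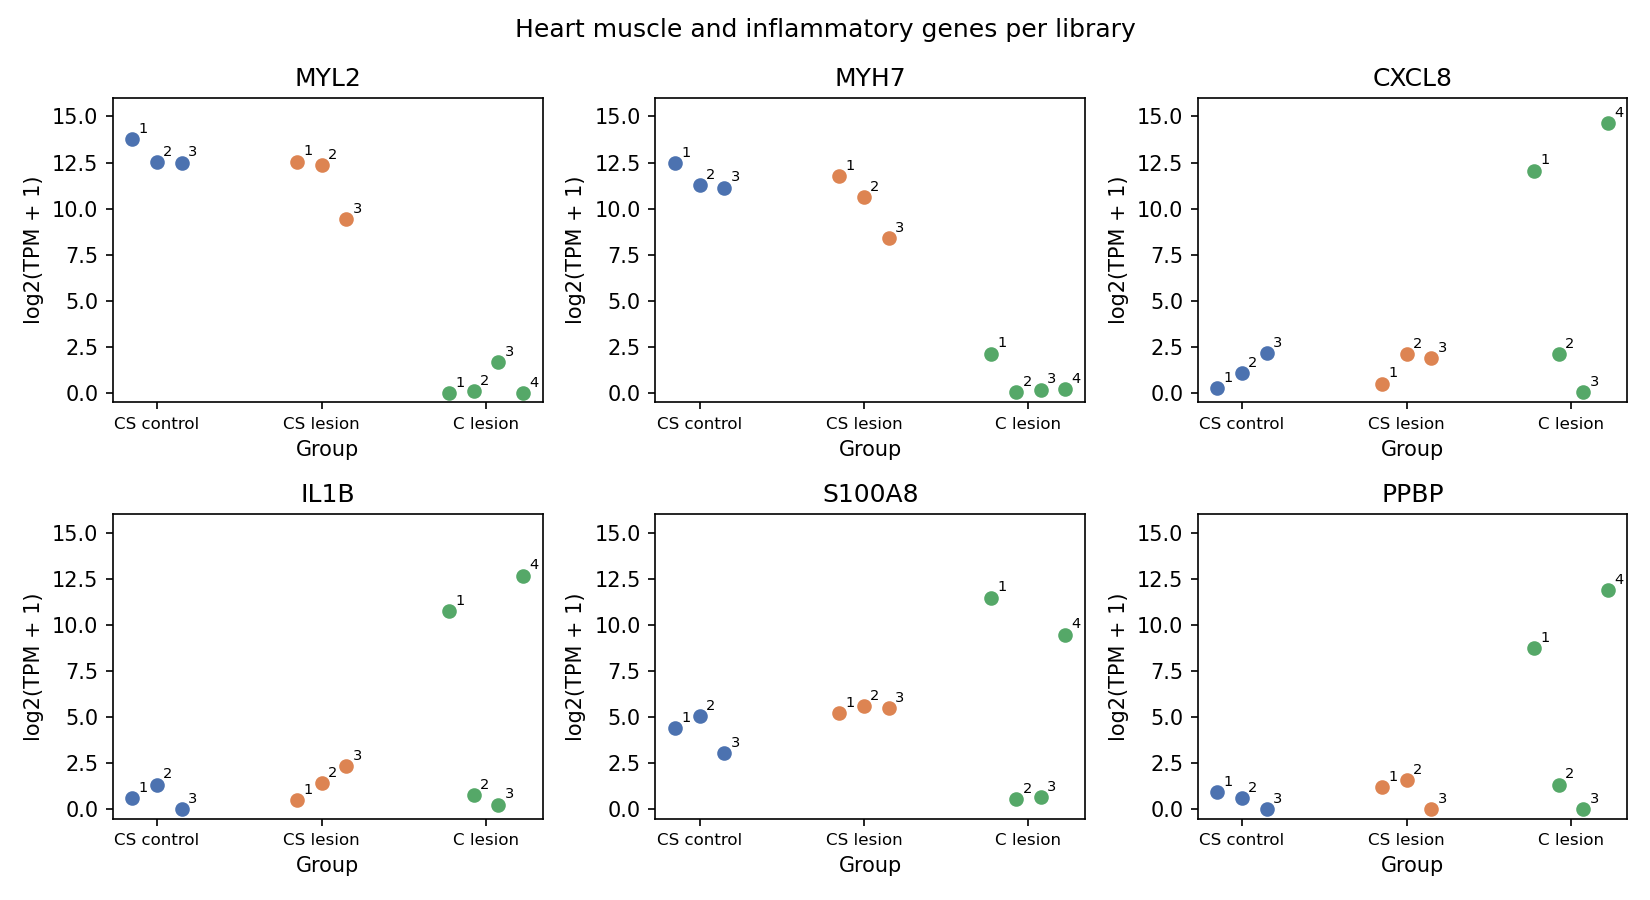
log2(TPM + 1) of MYL2, MYH7, CXCL8, IL1B, S100A8 and PPBP in each library (points, numbered by replicate) of the 3 groups. MYL2 is at 2.2 TPM or less in the C lesions and CXCL8 at 4266 and 25325 TPM in C lesions 1 and 4.

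The comparison of C lesion with CS lesion tested the difference between the 2 kinds of lesion. Of 28 sarcomere and calcium handling genes 26 fell in C lesions (adjusted p = 0.273 for the list with an estimated correlation). Of protein-coding TPM without the MTRNR2L family, this list held 0.0549%, 0.0489%, 0.489% and 0.0250% in C lesions 1 to 4. In CS lesions 1 to 3 it held 5.28%, 4.25% and 0.602%, so C lesion 3 lay close to CS lesion 3. Of plasma cell genes 10 of 17 fell and of T cell markers 5 of 21, beside a median of −1.95 over all genes, and without C lesions 2 and 3 these counts were 0 and 1 beside a median of −0.64 (adjusted p = 0.499 and 0.607 for the lists with an estimated correlation in all libraries, 0.459 and 0.688 without C lesions 2 and 3). In mean log2(TPM + 1) the plasma cell list stood at 2.37 in CS lesion 2 and 2.79 in C lesion 1. The T cell list stood at 1.94 in CS lesion 2 and 2.37 in C lesion 4. Both kinds of lesion thus overlapped in each list. MYL2 stood at 0.573 ± 1.09 TPM (SD, n = 4) against 3980 ± 2880 in CS lesions (n = 3), a log2 change of −10.99 ± 2.36 (SE; limma adjusted p = 0.00104). MB fell with a log2 change of −10.66 ± 2.25 (adjusted p = 0.000760) and TNNC1 with −9.99 ± 2.15 (adjusted p = 0.00107). DES, MYH7, ACTA1, ANKRD1, ACTC1 and FABP3 fell, with −9.83 to −8.92. IGHG3 fell with a log2 change of −4.90 ± 0.95 (adjusted p = 0.000182) and CD3E with −3.74 ± 0.88 (adjusted p = 0.00370). The ranges of IGHG3 overlapped, with 0.0473 TPM in CS lesion 2 and 1.79 TPM in C lesion 1. Without C lesions 2 and 3, CD3E kept its call (−3.47 ± 0.95, adjusted p = 0.0321) and IGHG3 did not (−4.53 ± 2.50, adjusted p = 0.421), with a change close to that in all libraries and a larger SE.

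Of 19562 genes, 8 rose and 878 fell (7516 at an unadjusted p under 0.05), with a median of −1.95, and without C lesions 2 and 3, 208 rose and 536 fell (median −0.64). Upper-quartile scaling gave 25 higher and 26 lower (median −0.06), median-of-ratios 15 and 104 (−0.48), and quantile normalization 22 and 61 (0.06). With no filter on low values limma called 1 gene, with 8029 at an unadjusted p under 0.05. Leaving out 1 library gave 13596 calls without C lesion 4, 385, 440 and 450 without C lesions 1, 2 and 3, and 43, 516 and 340 without CS lesions 1, 2 and 3. Among the 8 that rose, MTRNR2L13 (4.33 ± 1.28, adjusted p = 0.0293) and MTRNR2L7 (3.70 ± 1.14, adjusted p = 0.0377) lost their call without C lesions 2 and 3, and their group ranges overlapped. ADGRG3 and S100A12, genes of neutrophils, and CXCL1 did not pass, at 2.76 ± 0.96, 2.72 ± 1.11 and 3.42 ± 1.38. All 3 rose without C lesions 2 and 3, by 6.07, 6.57 and 7.93 (adjusted p = 0.000108, 9.75e-05 and 5.02e-07), and with array weights they turned to −0.38, −1.04 and −0.67. With these weights the median of all genes went to −3.30, and limma called 18818 genes lower.

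By camera 11 lists ranked higher and 11 lower, and 0 kept the call with an estimated correlation, against 10 calls of fry. Sarcomere and calcium handling genes had 26 of 28 members that fell, 28 adjusted over the list alone (mean −5.74, adjusted p = 4.64e-32; adjusted p = 0.273 with an estimated correlation). Among plasma cell and immunoglobulin genes 10 of 17 fell, 15 adjusted over the list alone (mean −2.26, adjusted p = 5.23e-10; adjusted p = 0.499 with an estimated correlation), and 0 fell in limma without C lesions 2 and 3. The mean not relative to all genes was −4.23, and −3.21 without these libraries (camera adjusted p = 6.90e-05; adjusted p = 0.459 with an estimated correlation). Of 21 T cell markers 5 fell, 16 adjusted over the list alone (mean −0.56, adjusted p = 8.78e-05; adjusted p = 0.607 with an estimated correlation), and 1 fell without these libraries, where the mean not relative to all genes went from −2.53 to −1.58 (camera adjusted p = 0.0118; adjusted p = 0.688 with an estimated correlation). Fibroblast markers had 8 of 16 members that fell, 15 adjusted over the list alone (mean −2.41, adjusted p = 4.65e-08; adjusted p = 0.499 with an estimated correlation), with DPT, the matrix protein dermatopontin, down by −5.22 ± 1.21 (adjusted p = 0.00336). Of protein-coding TPM without the MTRNR2L family, fibroblast markers held 0.0244%, 0.377%, 0.348% and 0.0367% in C lesions 1 to 4, against 0.0961% to 0.483% in CS lesions. Extracellular matrix genes had 13 of 27 that fell, 18 adjusted over the list alone, such as POSTN, the matrix protein periostin (−5.35 ± 1.39, adjusted p = 0.0109). Their mean of −1.95 (adjusted p = 9.17e-08; adjusted p = 0.553 with an estimated correlation) turned to 0.055 with upper-quartile scaling.

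The bacterial sensing and NF-kB list ranked above other genes (mean 2.28, adjusted p = 5.31e-25; adjusted p = 0.404 with an estimated correlation), and 0 of 30 members rose in limma, over all genes or adjusted over the list alone. Without C lesions 2 and 3, 14 rose and 25 adjusted over the list alone (adjusted p = 0.0505 with an estimated correlation). Neutrophil and platelet lists had means of 2.14 and 3.10 (adjusted p = 1.53e-14 and 1.27e-12; adjusted p = 0.404 and 0.273 with an estimated correlation), and without C lesions 2 and 3 these were 0.0128 and 0.0220 with an estimated correlation. Erythrocyte genes had a mean of 1.10 (adjusted p = 0.00128; adjusted p = 0.572 with an estimated correlation). Not relative to all genes, the erythrocyte mean was −0.87, with 7 of 9 members lower, and 1.36 without C lesions 2 and 3. Of the lists that ranked higher, 8 had a mean log2 change below 0 before it was set against all genes, and 10 a median below 0, while without C lesions 2 and 3 the mean was above 0 in all 11.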

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

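The alignment to mitochondrial ribosomal RNA and the share of heart muscle mRNA were tests chosen after the values they explain had been seen, and the splits of the samples were planned.

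In the C lesions, 12 of 81 values tested had 1 library far from the other 3, and chance flags about 1 in 20 groups. That rate does not hold here, since in most of these the other libraries were listed at or near 0, where a single value above 0 stands apart by construction. C lesion 1 held the highest immunoglobulin share (0.0863%), IGHG3 (1.79 TPM), IGHG4 (1.35 TPM), SYNDIG1 (0.830 TPM), MYH7 (3.40 TPM), ACTA1 (9.12 TPM) and ACTC1 (23.2 TPM). C lesion 3 held the highest MYL2 (2.2 TPM), MB (0.767 TPM) and TNNC1 (0.618 TPM), and C lesion 4 the highest RBP2 (49.0 TPM) and FABP3 (4.92 TPM).

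The test of the difference between C lesion and CS lesion passed for 22 lists by camera, with means given as log2 difference relative to all genes. With an estimated correlation 0 of them passed, against 10 by fry. Ranked lower in C lesions were the lists of the sarcomere (−5.74), cardiac stress program (−4.67), fibroblasts (−2.41), nuclear oxidative phosphorylation (−2.38), plasma cells (−2.26), fatty acid oxidation (−2.04), extracellular matrix (−1.95), smooth muscle and pericytes (−1.75), endothelium (−1.34), adipocytes (−0.98) and T cells (−0.56). Ranked above other genes were those of platelets (3.10), bacterial sensing and NF-kB (2.28), neutrophils (2.14), inflammasome (1.53), antimicrobial effectors (1.17), erythrocytes (1.10), metalloproteinases and cathepsins (0.92), cell cycle (0.89), granuloma (0.86), immediate early genes (0.23) and macrophages (0.070). Of the 198 tested members of these 11 lists, limma called 0 higher, with 7 higher and 17 lower at an unadjusted p under 0.05, and without C lesions 2 and 3, 40 rose and 2 fell. Before they were set against all genes, 8 of the 11 had a mean below 0, among them macrophages (−1.90, with 25 of 26 members lower) and immediate early genes (−1.74, with 23 of 26 lower). These means turned to 1.17 and 0.92 without C lesions 2 and 3, where the mean was above 0 in all 11, and 3 of the 11 passed with an estimated correlation.

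C lesions 2 and 3 held nearly all of their TPM in a few IDs. Their 3 IDs that align to MT-RNR2, with identities of 91.0% to 95.0%, held at least 77.1% of the TPM in both, against 26.0% in C lesion 1, 0.833% in C lesion 4 and 3.63% or less in the CS libraries, so a candidate explanation is mitochondrial 16S ribosomal RNA counted on nuclear copies. The heart muscle list held at most 0.489% of the protein-coding TPM left in these libraries, under the lowest CS control (3.76%), which argues against too little mRNA from heart muscle of a composition like the CS controls. The share was 0.0549% and 0.0250% in C lesions 1 and 4 and 0.602% in CS lesion 3, so a low share does not set C lesions 2 and 3 apart from the other C lesions. The tissue sampled, its decay and the depletion of ribosomal RNA stay open, and no biological explanation was tested.

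Other splits of the same samples show how far the counts of called genes rest on single libraries. For CS lesion against CS control, 4 of 10 splits called as many genes as the real one, with 22 in the real split and 120 in the highest other, and 10 splits are too few for a share under 0.05. These splits ignore the pairing by case. The 3 other splits that part all 3 cases, as the real one does, called 0 to 23 genes, and the 6 that part 1 case called 2 to 120 and also carry differences between cases. For C lesion against CS control, 2 of 35 splits called as many, with 1206 real and 11565 in the highest other, so chance was not excluded. For C lesion against CS lesion, 4 of 35 did, with 886 real and 13674 in the highest other, and chance was not excluded. In both of these the highest split moved C lesion 4 to the other group, which points to a structure of the samples beyond the groups. That split set C lesions 1 to 3 against libraries with 3.63% or less of TPM in IDs that align to MT-RNR2. C lesions 1 to 3 held 26.0%, 77.9% and 77.1% there, so its count does not show chance alone.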

How the results depend on the processing

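The leaving out of C lesions 2 and 3 and the removal of ribosomal RNA-like IDs (the MTRNR2L family and AC114801.3) were chosen after seeing the data. Single genes and lists kept their direction and side of the threshold in 714 of the CS lesion against CS control values, 838 of the C lesion against CS control values and 761 of the C lesion against CS lesion values, lost the call in 117, 150 and 135, gained it in 10, 13 and 12, and reversed in 1, 20 and 16. For CS lesion against CS control, the plasma cell and T cell lists kept their camera call in all 25 settings with the preset correlation (means 1.62 to 3.74 and 0.85 to 1.98), and lost it with an estimated correlation (adjusted p = 0.453 and 0.601) and by fry (0.960 for both). Unknown depth limits all low values. Where no cause is given, the cause was not tested.

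The 22 genes called for CS lesion against CS control became 2 with both groups alone, 1 with upper-quartile, 2 with median-of-ratios and 2 with quantile scaling, 2 at 5 TPM, 67 with array weights, 4 and 3 with pseudocounts of 0.1 and 5, 3 without C lesions 2 and 3, 1 without ribosomal RNA-like IDs and 2 with both of these. Limma called 0 with no filter (783 at an unadjusted p under 0.05) and 0 without trend (129). Leaving out 1 sample gave 0 to 90, 0 (204 unadjusted) without CS lesion 1 90 without CS lesion 2, 2 without CS lesion 3, 3, 4 and 12 without CS controls 1, 2 and 3, and 7 without C lesion 4. The replicate block, which pairs the samples of a case, gave 0 as a fixed term and 592 as a random one, and the lists went from 20 to 28 with the fixed block.

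The 1206 genes of C lesion against CS control became 757 with both groups alone, 777 with upper-quartile scaling, 593 with no filter, 18204 with array weights, 1978 without mitochondrial mRNAs and 628 without ribosomal RNA-like IDs. Leaving out 1 sample gave 105 (without CS control 1) to 11007 (without C lesion 4), with 599 and 727 without CS controls 2 and 3, 678 without CS lesion 3, and 677, 626 and 626 without C lesions 1, 2 and 3. The 886 genes of C lesion against CS lesion became 51, 119 and 83 with upper-quartile, median-of-ratios and quantile scaling, 1 with no filter, 18834 with array weights, 117 with a pseudocount of 5, 1380 without mitochondrial mRNAs and 140 without ribosomal RNA-like IDs, and 43 (without CS lesion 1) to 13596 (without C lesion 4) when 1 sample was left out, with 516 and 340 without CS lesions 2 and 3, and 385, 440 and 450 without C lesions 1, 2 and 3.

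The lists past the threshold were 20, 26 and 22. No filter gave 13 and 16 in the first and second comparison. An estimated correlation gave 0, 0 and 0 and fry gave 0, 9 and 10. Leaving out 1 sample gave 13 to 22 in the first, 13 without CS control 1.

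The extracellular matrix list of C lesion against CS control turned to 0.56 with upper-quartile and 0.26 with median-of-ratios scaling and to 0.13 without ribosomal RNA-like IDs. Against CS lesion it turned to 0.055 with upper-quartile scaling, and at −0.26 with median-of-ratios scaling only the test turned. Array weights turned BCL2A1 (−0.10) and CCL3 (−0.16) against CS control, and ADGRG3 (−0.38), S100A12 (−1.04), CXCL1 (−0.67), macrophage markers (−1.67) and immediate early genes (−1.06) against CS lesion. The median of all genes with these weights was −3.04 against CS control and −3.30 against CS lesion. The dendritic cell list of CS lesion against CS control ranged from −0.068 (without CS lesion 3) to 0.88, and the erythrocyte list of C lesion against CS control from −0.27 (without C lesion 1) to 0.98.

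Fry tests a list alone and not against other genes, so by construction a list can rank above other genes and still turn, and all lists that turned had a median below 0. For C lesion against CS control their means were −0.25 (metalloproteinases and cathepsins), −1.08 (erythrocytes), −0.93 (T cells), −0.78 (cytotoxic), −0.38 (B cells), −0.38 (macrophages), −0.20 (granuloma), −0.45 (eosinophils), −0.87 (interferon gamma), −0.99 and −0.89 (MHC class I and II), 0.26 (inflammasome, median −0.54), −0.011 (antimicrobial) and −0.70 (cell cycle). For C lesion against CS lesion they were −1.05 (metalloproteinases and cathepsins), −0.87 (erythrocytes), −1.90 (macrophages), −1.11 (granuloma), 0.31 (bacterial sensing and NF-kB, median −0.29), −0.44 (inflammasome), −0.80 (antimicrobial), −1.08 (cell cycle) and −1.74 (immediate early genes).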

Other observations

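The comparisons of lists within cases and the search for noncoding RNA in abundant transcripts were tests chosen after the patterns had been seen.

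Several immune lists not described so far were also higher in CS lesions by camera. Lymphoid chemokines had a mean log2 change of 1.02 relative to all genes (adjusted p = 4.38e-05), with 10 of 11 members higher. B cell markers had a mean of 0.65 (adjusted p = 0.000379), with CD79A, a chain of the B cell receptor, at a log2 change of 2.33 ± 0.78 (SE; limma adjusted p = 0.600). Granuloma and giant cell genes had a mean of 0.71 (adjusted p = 0.00451), with CHIT1, a chitinase of activated macrophages, at 2.58 ± 1.07, and the bacterial sensing and NF-kB list 0.70 (adjusted p = 0.00408), with NOD2, a sensor of bacterial cell walls, at 1.91 ± 1.03. For all 4 lists the adjusted p = 0.808 with an estimated correlation, and type I interferon response genes did not pass (0.29, adjusted p = 0.173).

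SPP1, the macrophage and matrix protein osteopontin, stood at 31178 TPM in C lesion 4, 139 TPM in C lesion 1 and 571 TPM in CS lesion 3. S100A8, a calcium-binding protein of neutrophils, stood at 2849 and 712 TPM in C lesions 1 and 4 and at 47.6 TPM or less in every other library. MMP12, a macrophage elastase, stood at 2063 TPM in C lesion 4 and at 13 TPM or less elsewhere. Values of C lesions 2 and 3 are lowered by the IDs that resemble ribosomal RNA. Of protein-coding TPM without the MTRNR2L family, the neutrophil list held 1.87%, 0.125%, 0.0373% and 0.506% in C lesions 1 to 4. In the CS libraries it held 0.0102% to 0.0479%.

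By camera, immune lists ranked higher and heart muscle lists lower in CS lesions, with 0 of 38 lists past the threshold under an estimated correlation (adjusted p = 0.453 or more) or by fry. A lower share of heart muscle RNA alone would raise T cell and endothelial markers alike, but the change of the T cell list exceeded that of the endothelial list by 1.74 ± 0.96 (SD over 3 cases), which argues against it as the whole cause. More blood in the lesion sections would raise erythrocyte genes, but their change lay below 0.5 times that of the T cell list by a mean difference of −1.01 ± 0.17, which argues against it too. More immune cells in the lesions may be the cause, as a hypothesis, while differences in RNA decay between sites and lower expression within muscle cells stay open.

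Transcripts in none of the gene lists, such as WDR74, PCSK5 and ZPR1, were among the 20 most abundant nuclear IDs. The ranking used the mean share of TPM over the 8 libraries without C lesions 2 and 3, and left out the MTRNR2L family and AC114801.3. Single libraries differed widely, with PCSK5 at 0.00520% to 7.42% and ZPR1 at 0.0931% to 7.75% of TPM. Of the 20 IDs, 4 hold a nearly whole noncoding RNA (WDR74 with RNU2-2P, AC104996.3 with RNY4P13, ZNF354B with RNU1-39P and EIF4A1 with SNORD10), against 7 of 935 length-matched genes, or 0.749% (Fisher's exact p = 4.22e-05), so their values may come from reads of these noncoding RNAs. For 10 other IDs outside the gene lists, partial matches were found in 5, against 315 of 928 length-matched genes, or 33.9% (Fisher's exact p = 0.322), and for these a partial match and an ordinary transcript cannot be told apart with so few IDs. No biological explanation was tested.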
